A study of Homo sapiens with 6 samples.

How the data were processed

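RNA was measured in mitochondria isolated from HepG2 cells after 48 h with 0, 10 or 100 µM GenX, in 2 libraries per dose and 6 in all. The values used were raw counts of reads per gene, whole numbers, as deposited, 1 table per library in the layout that featureCounts writes. Per the submitters' processing notes, the tools involved were FastQC, STAR, featureCounts and DESeq2 with the GRCh38 build, with no version given. The annotation release, the strand setting, and the treatment of overlapping or multiply mapped reads were not given in the sources used here. Per the labels' protocols the libraries were stranded, made from total RNA and depleted of ribosomal RNA. The kit, the depletion and the handling of overlaps can each change the counts of short and overlapping mitochondrial genes.

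Each table listed 57500 genes by identifier, with chromosome, start and end, and 0 lines that named no gene. Symbols and gene types came from GENCODE v29, which held 56898 of the identifiers, 54773 of them with the same start and end. A total of 37868 genes had no count in any library. The 35 mtDNA genes in the tables were 13 protein-coding and 22 transfer RNA genes, and the mitochondrial ribosomal RNA genes were not analysed here. Groups and replicate numbers were taken from the sample titles, and 0 columns were left without a sample.

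Library totals ran from 29350 to 2141282 counts. A gene at 0 was taken to lie below the level of 3 counts, and shares of counts carry an exact 95% binomial interval. Folds for a gene without a count in a group used 3 counts over that group's pooled total and took the other group's counts as measured, and ratios for a gene with 1 to 3 counts in a group carry an exact 95% counting interval. Before averaging, replicates were compared by a chi-square test over genes with at least 10 counts. The statistic per degree of freedom was 39.4 in the controls, 12.9 at 10 µM and 35.2 at 100 µM, so no pair agreed within sampling noise, and log2 CPM of tested genes correlated at 0.347, 0.345 and 0.810.

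The main test was edgeR 4.0.16 in R 4.3.3, with filterByExpr on the groups (3180 genes kept), TMM scaling over all kept genes, robust quasi-likelihood fits of all 6 libraries in 1 model of group means, and two-sided tests of 3 comparisons. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Fitting the groups together gave them 1 shared estimate of the spread. Gene lists, 39 in all, were written before the data were examined, and 29 with at least 5 tested members entered camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. Calls were also made with a correlation estimated per list and with fry, which asks whether a list's genes move 1 way and does not compare them with other genes. Shares of counts were compared by exact two-sided permutation tests in scipy 1.17.1, with tables handled in pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15, and plots drawn with matplotlib 3.10.9.

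Genes were named by a fixed rule. In each comparison these were the 8 protein-coding genes with the largest log2 fold change in each direction among those that passed, with both libraries of the higher group above both of the lower and a mean of at least 10 CPM in the higher group. Where none passed in a direction, the 4 with the smallest p were given as values. In each list that camera called, and in 5 lists fixed for naming, up to 3 members that passed were named, or the member with the highest mean CPM. All mtDNA protein genes could be named. A gene that met the rule at 100 against 10 µM is not reported here. The rule's first part was met by 7 genes higher and 10 lower at 10 µM against control, and by 22 higher and 39 lower at 100 against 10 µM.

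The scripts were tested on counts simulated from the real means and library sizes with 200 genes changed by known folds. At 10 µM against control 0% of genes changed 4-fold or 16-fold and 10.6% of those changed 64-fold were recovered, with 1 unchanged gene called. At 100 µM against control the shares were 1.49%, 7.46% and 50.0%, with 10 unchanged genes called, and at 100 against 10 µM 0%, 0% and 40.0%, with 2. A raised list was called in all 3 comparisons and 0 of 30 unchanged lists were. Genes were simulated independently of each other, so this does not test the list calls where genes are correlated. In the data the estimated correlation was 0.679 for the mtDNA protein list and 0.00537 for the large-subunit ribosomal list.

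Alternatives to each choice were DESeq2 size factors, library sizes alone, TMM without mtDNA genes, DESeq2 1.42.0 with its Wald test, no filter on low counts, a mean of at least 5 CPM, only the 4 libraries compared, a replicate block, a minimum log2 change of 1, scaling to the mtDNA protein genes, and leaving out each library in turn. Thinning every library to the shallowest total and leaving out the 10 most abundant genes of each library were added after the data were seen. Correlations of fold changes were set beside 30 simulations of unchanged groups against the same controls.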

Results

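The series measured RNA from mitochondria of HepG2 cells, a human liver carcinoma line used as a stand-in for hepatocytes. The cells were exposed for 48 h to GenX, the trade name of a short-chain perfluoroalkyl ether acid that replaced perfluorooctanoic acid in fluoropolymer production. Doses were 0, 10 and 100 µM, with the solvent DMSO alone as the control, and there were 2 libraries per dose, 6 in all. Mitochondria were isolated with a kit, their total RNA was extracted, ribosomal RNA was depleted, and stranded libraries were sequenced. The stated aim was to compare mitochondrial gene expression across doses.

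Depth differed strongly between groups. The 2 controls held 240683 and 60854 counts on genes, the 10 µM libraries 43556 and 29350, and the 100 µM libraries 2141282 and 1338397, a 73.0-fold range from the shallowest to the deepest. Genes with at least 1 count numbered 8226 and 5210 in the controls, 4665 and 3100 at 10 µM, and 13708 and 11673 at 100 µM. A gene without a count may still have reached 12.5 and 49.3 CPM (counts relative to the library total) in the controls, 68.9 and 102 CPM at 10 µM, and 1.40 and 2.24 CPM at 100 µM, the level of 3 counts. Intervals and limits of this kind cover counting error only. The labels gave all 6 libraries 1 batch and did not say whether the replicates came from separate cultures, so p-values measured only the spread between these samples, which may be technical.

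Genes encoded by mitochondrial DNA (mtDNA) took 4.35% of the counts in control 1 (95% exact binomial interval 4.27 to 4.43) and 10.4% in control 2 (10.2 to 10.7). At 10 µM they took 43.7% (43.3 to 44.2) and 61.1% (60.6 to 61.7), and at 100 µM 3.58% (3.56 to 3.61) and 3.32% (3.29 to 3.35). Group means were 7.39% ± 4.30 (SD, n = 2) in the controls, 52.4% ± 12.3 at 10 µM and 3.45% ± 0.187 at 100 µM. The 10 µM mean was 45.0 percentage points above the control mean, and the 100 µM mean differed from the control mean by -3.94 points and from the 10 µM mean by -49.0 points. Each of the 3 comparisons gave p = 0.333 in an exact two-sided permutation test, the smallest that 2 against 2 libraries can reach. The 35 mtDNA genes counted were the 13 protein-coding genes, all of them subunits of the respiratory chain or ATP synthase, and the 22 transfer RNA genes. The ribosomal genes MT-RNR1 and MT-RNR2 were not analysed here.

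**Figure D1:**
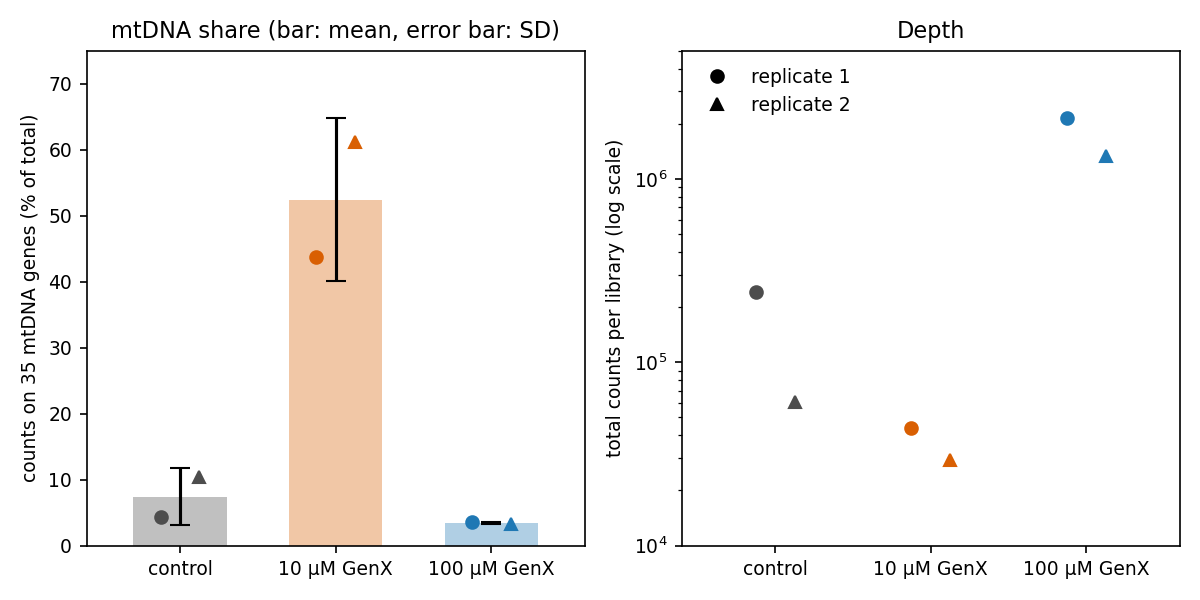
Share of counts on 35 mtDNA genes in percent (left, bars are group means and error bars the SD of 2 libraries) and total counts per library on a log axis (right), with a circle for replicate 1 and a triangle for replicate 2. The 10 µM libraries had the highest mtDNA shares, 43.7% and 61.1%, and the lowest totals, 43556 and 29350.

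How counts were spread over the 13 mtDNA protein genes also differed between doses. At 100 µM the cytochrome c oxidase subunit MT-CO1 took 34.8% and 32.6% of the counts on these genes, against 17.5% and 11.98% in the controls and 13.6% and 13.1% at 10 µM. MT-CO2, another subunit of this enzyme, took 24.9% and 19.4% in the controls, 6.27% and 6.53% at 10 µM, and 17.8% and 18.7% at 100 µM. MT-ND5, a complex I subunit, took 7.30% and 13.02%, then 16.7% and 15.7%, then 3.39% and 2.66%. Per kilobase of gene, the 10 µM libraries held between 1109 and 1923 counts on each of the 13 genes in replicate 1 and between 1075 and 1592 in replicate 2. The 100 µM libraries ranged from 379 to 19427 and from 382 to 11756, and the controls from 227 to 3465 and from 269 to 1585. The SD of log2 counts per kilobase over the 13 genes was 0.229 and 0.198 at 10 µM, 1.03 and 0.611 in the controls, and 1.77 and 1.59 at 100 µM. MT-ND6, the only protein gene on the minus strand, held 1661 and 1550 counts per kilobase at 10 µM, beside 1456 and 1364 for the other 12 genes together. At 100 µM it held 1417 and 1055 beside 6804 and 3908, and in the controls 556 and 476 beside 850 and 492. With the counts on the 13 genes as the library size, 1 gene passed in edgeR's quasi-likelihood test with adjustment over these 13 genes. MT-ND5 was lower at 100 than at 10 µM (log2 fold change -2.42, adjusted p = 0.0332), and against control the smallest adjusted p was 0.0628 at 10 µM (MT-CO2, -1.79) and 0.117 at 100 µM. Adjusted over all genes tested on this scale, MT-CO2 passed at 10 µM against control (0.0316), and MT-ND2, MT-ND3, MT-ND5, MT-ND6, MT-CO1 and MT-CO2 passed at 100 against 10 µM (0.0105 to 0.0424). On this scale MT-CO1 (1.34), MT-CO2 (1.51), MT-CO3 (0.64) and MT-ND4 (0.31) had values above 0 at 100 against 10 µM, and the 10 µM values against control lay between -1.79 and 0.96.

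**Figure D2:**
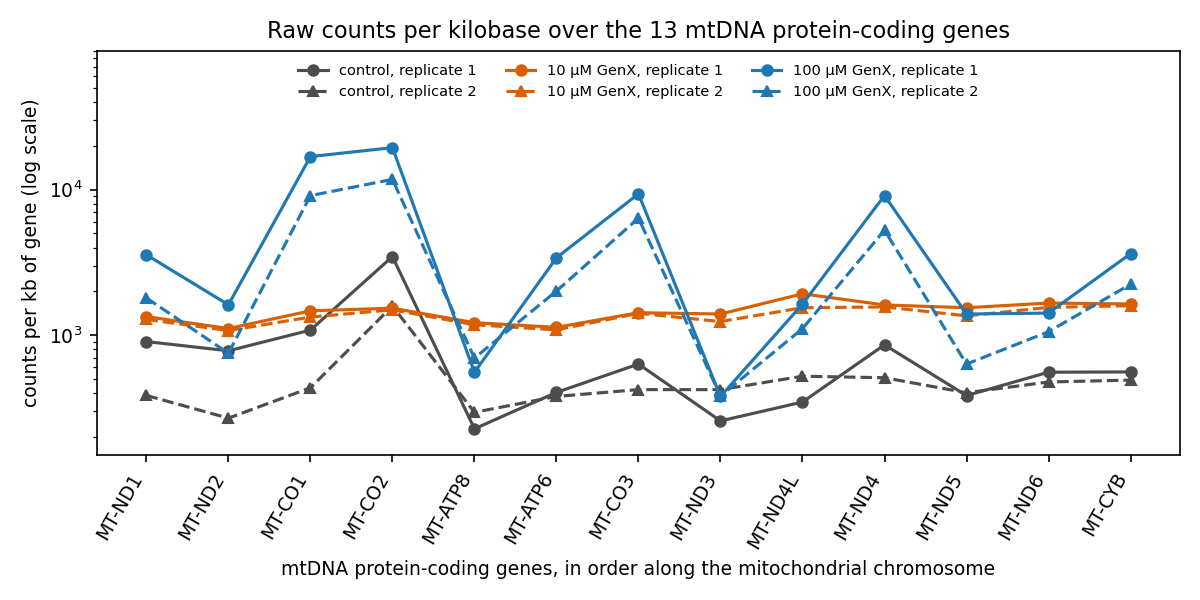
Raw counts per kilobase of gene (log axis) over the 13 mtDNA protein-coding genes in chromosome order, with 1 line per library. Both 10 µM lines stay between 1075 and 1923 counts per kilobase, while the 100 µM lines span 379 to 19427.

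At 10 µM against control, 7 mtDNA protein genes were higher and 12 nuclear genes lower. MT-ND5 rose by 3.22 ± 0.54 log2 units (SE, n = 2 per group; adjusted p = 0.0372 in edgeR's quasi-likelihood test), from 7427 ± 6414 to 73948 ± 13860 CPM (SD). The rise was 2.65 without control 1 and 4.20 without control 2. MT-CO1 rose by 2.55 ± 0.40 (adjusted p = 0.0284), from 8972 ± 2882 to 60958 ± 12666 CPM. Among nuclear genes, NDRG1, which responds to hypoxia and cell stress, had a log2 fold change of -6.39 ± 0.77 (adjusted p = 0.00959), and APOA2, an apolipoprotein of high-density lipoprotein secreted by hepatocytes, -6.30 ± 0.82 (adjusted p = 0.0111). In all, 3180 genes were tested.

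The 7 higher genes were MT-ND1 (2.68), MT-ND2 (2.78), MT-ND4 (2.75) and MT-ND5 of complex I, MT-CYB (3.02, then 2.53 without control 1 and 3.83 without control 2) of complex III, and MT-CO1 and MT-CO3 (2.93) of complex IV. The SEs lay between 0.40 and 0.54 and the adjusted p-values between 0.0284 and 0.0414. MT-CO2 (0.89, adjusted p = 0.195), MT-ATP6 (2.88, 0.0813), MT-ATP8 (3.48, 0.120), MT-ND3 (3.16, 0.119), MT-ND4L (3.21, 0.105) and MT-ND6 (3.05, 0.0669) did not pass, and without control 2 the last 5 values were 3.75, 4.69, 4.64, 4.59 and 3.82. Without control 1, MT-ATP6, MT-ATP8, MT-ND3, MT-ND4L and MT-ND6 had 2.36, 2.83, 2.44, 2.52 and 2.56. Adjusted over the list alone, 12 of the 13 were higher, with a list median of 2.93. In camera, which compares a list with all other genes, this list ranked higher (adjusted p = 1.14e-11, and adjusted p = 0.416 with an estimated correlation). Of the 22 mitochondrial transfer RNA genes, 0 passed over all genes and 13 were higher adjusted over the list alone, with a median of 3.28. That list also ranked higher (adjusted p = 3.62e-17, and adjusted p = 0.377 with an estimated correlation), and its member with the highest level, MT-TV, had a value of 3.51 (adjusted p = 0.106), or 2.87 without control 1 and 4.71 without control 2. These changes stood beside the near-even counts per kilobase over mtDNA genes at 10 µM, with an SD of 0.229 and 0.198.

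Nuclear genes lower at 10 µM than in the controls came from several functions. HNRNPH1, a splicing regulator on chromosome 5 (GRCh38 179614178 to 179634784), had 1921 and 118 counts in the controls and 0 in both 10 µM libraries, at least 121-fold lower over the groups and 47.1-fold with control 2 alone (adjusted p = 0.0284). AHNAK, a large scaffold protein, had 407 and 112 counts against 0 and 0, at least 42.9-fold lower (lower 95% counting limit 33.9, adjusted p = 0.0489). The epithelial keratins KRT19 and KRT18 had pooled control to 10 µM ratios of 175 (95% counting interval 31.2 to 6904, 1 count at 10 µM) and 93.4 (25.8 to 773, 2 counts), with adjusted p = 0.0414 and 0.0410. SAT1, which acetylates polyamines, had 6636 and 216 counts in the controls and a log2 fold change of -7.12 (adjusted p = 0.0284), then -4.50 without control 1 and -7.97 without control 2. AKAP12, an anchor of protein kinase A, had -6.86 ± 1.03 (adjusted p = 0.0270), then -5.77 without control 1. These counts came from libraries in which MALAT1, a long RNA kept in the nucleus, took 0.0390% and 0.0443% of the counts at 10 µM, against 13.5% and 4.61% in the controls. Whether the mitochondrial preparations of both groups held like amounts of nuclear and cytosolic RNA was not tested.

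Of the gene lists fixed in advance, 29 had enough tested members, and 6 ranked apart from the other genes, 2 higher and 4 lower. Both lists that ranked higher were the mtDNA lists. Of 24 genes of glycolysis and the hypoxia response, 1 was lower over all genes (NDRG1) and 15 adjusted over the list alone. Their median was -4.68, or -3.66 with the 6 members at 0 in a group set to their bound (camera, adjusted p = 0.00039, then 0.0628 without control 2, and adjusted p = 0.251 with an estimated correlation). Of 11 proteins secreted by hepatocytes, 1 was lower (APOA2) and 6 adjusted over the list alone, with a median of -5.84, or -4.01 at the bound of 3 members (adjusted p = 0.0318, then 0.211 without control 1, 0.167 without control 2, and adjusted p = 0.377 with an estimated correlation). Of 44 large-subunit and 31 small-subunit proteins of the cytosolic ribosome, 0 passed over all genes and 19 and 22 were lower adjusted over the list alone. Their medians were -5.04 and -5.43, or -3.81 and -4.37 with 14 and 10 members at their bound. Both lists ranked lower in camera (adjusted p = 2.74e-07 and 2.27e-06, and adjusted p = 0.251 for both with an estimated correlation). On camera's log2 scale with a prior count, genes at 0 share a floor, and 1286 tested genes had no count at 10 µM. The fall of such a gene was capped by its control level above that floor. Lists of abundant genes thus had more room to rank lower than lists of less abundant genes. Whether abundance accounts for the 4 lower ranks was not tested. RPL37A had a log2 fold change of -4.32 (adjusted p = 0.120), between -6.10 and -3.43 without a library, and RPS3 -5.40 (adjusted p = 0.105), between -6.68 and -4.46.

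The nuclear-encoded mitochondrial lists did not rank apart in camera at 10 µM against control. Tested against no change by fry, while the median of all genes was -3.18, complex I (adjusted p = 0.0483) and complexes II to V (0.0128) were among 20 lists called lower. Of 17 complex I genes 0 passed, with a median of -6.17, or -0.27 with 7 members at their bound (camera, adjusted p = 0.828). NDUFB9 had a control to 10 µM ratio of 43.6 (11.99 to 362, 2 counts at 10 µM; adjusted p = 0.127), and the log2 value of -6.70 became -2.50 without control 2 and -14.24 without 10 µM replicate 1. Of 30 genes of complexes II to V 0 passed over all genes and 1 was lower adjusted over the list alone, with a median of -7.14, or -0.81 with 18 members at their bound (adjusted p = 0.110, then 0.0245 without 10 µM replicate 2). COX4I1 of cytochrome c oxidase had a ratio of 80.3 (14.3 to 3180, 1 count; adjusted p = 0.103). Of 9 genes of mtDNA transcription and RNA processing 0 passed (adjusted p = 0.828), and their median of -0.33 differed in sign from the test's direction and from the 0.97 obtained with 4 members at their bound. LRPPRC, which stabilises mitochondrial mRNAs, had a 10 µM to control ratio of 15.2 (4.01 to 84.7) that rested on 11 counts in a single 10 µM library and 3 in control 1 (adjusted p = 0.245). Of 18 integrated stress response genes 0 passed over all genes and 2 were lower adjusted over the list alone, with a median of -5.33, or -1.53 at the bound (adjusted p = 0.369). STC2 had a control to 10 µM ratio of 35.1 (6.19 to 1394, 1 count; adjusted p = 0.146). Its log2 value was -2.21 without control 1 and -11.63 without 10 µM replicate 1. Of 10 targets of PPARα, the lipid-sensing receptor, 0 passed and 1 was lower adjusted over the list alone, with a median of -5.40, or 0.87 at the bound, and a downward test (adjusted p = 0.933). ANGPTL4, a secreted inhibitor of lipoprotein lipase, had a ratio of 38.3 (10.5 to 318, 2 counts; adjusted p = 0.0813).

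The median log2 fold change of all genes was -3.18 with TMM, -2.66 with DESeq2 size factors and -2.64 with library sizes alone. The values given here include that shift, and 1286 of the tested genes had no count at 10 µM. The split of 7 higher and 12 lower became 8 and 7 with DESeq2 size factors, 0 and 7 with library sizes alone, and 3 and 12 in DESeq2's Wald test, which shared 1 gene, and the calls numbered 0 without either 10 µM library, 245 without control 1 and 624 without control 2.

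**Figure D3:**
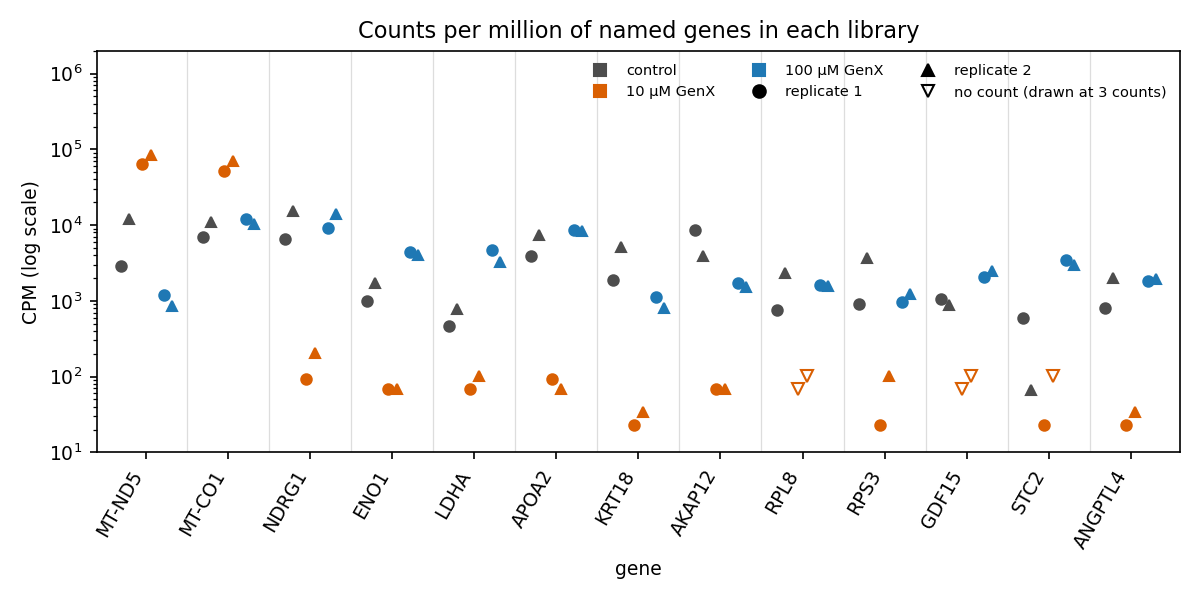
CPM of 13 named genes in each of the 6 libraries on a log axis, with colour for the dose, a circle for replicate 1, a triangle for replicate 2 and an open triangle at the level of 3 counts for a gene without a count. NDRG1 sat at 148 ± 79.6 CPM (SD, n = 2) at 10 µM and 10827 ± 6092 in the controls, while MT-ND5 sat at 73948 ± 13860 and 7427 ± 6414.

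At 100 µM against control, 0 of 3180 genes passed in edgeR's quasi-likelihood test, where 573 had an unadjusted p under 0.05, 381 higher and 192 lower. DESeq2's Wald test called 11, all lower and 0 of them mtDNA genes. Among protein-coding genes with lower values in edgeR that met the naming rule, the smallest p-values belonged to complex I subunits encoded by mtDNA. Transfer RNA genes such as MT-TV lie outside this ranking. MT-ND2 had 685 ± 143 CPM (SD, n = 2) at 100 µM and 3990 ± 865 in the controls, a log2 fold change of -3.12 ± 0.51 (adjusted p = 0.115). The values were -3.31 ± 0.55 for MT-ND5 (adjusted p = 0.115), -3.27 ± 0.62 for MT-ND6 (0.166) and -4.51 ± 0.88 for MT-ND3 (0.166), and without control 2 they were -2.25, -2.42 and -2.96, while MT-ND3 had -5.23 without control 1. Among genes with higher values, H3-3B, which encodes the replacement histone H3.3, had 4190 ± 711 CPM against 178 ± 4.42 (3.94 ± 1.04, adjusted p = 0.204).

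Of the 13 mtDNA protein genes, 0 passed over all genes and 11 were lower adjusted over the list alone, with a median of -2.29. The list ranked lower in camera (adjusted p = 1.22e-08, and adjusted p = 0.692 with an estimated correlation). The other values were -2.29 for MT-ND1, -1.72 for MT-CO2, -1.81 for MT-ATP6, -3.30 for MT-ATP8, -3.06 for MT-ND4L, -1.05 for MT-ND4, -2.09 for MT-CYB, -0.56 for MT-CO3 and -0.22 for MT-CO1, and without control 2 they were -0.87 for MT-ATP6, -2.02 for MT-ATP8, -1.60 for MT-ND4L, -1.21 for MT-CYB and 0.050 for MT-CO3, while without control 1 MT-ATP8 and MT-ND4L had -3.96 and -3.75. MT-CO1 alone turned upward under another scaling to all genes, to 0.33 with library sizes only. Scaled to the 13 genes themselves, MT-CO1 (1.19), MT-CO3 (0.94) and MT-ND4 (0.43) had values above 0. Of the 22 mitochondrial transfer RNA genes, 0 passed over all genes and 21 were lower adjusted over the list alone, with a median of -5.52 (camera, adjusted p = 6.50e-25, and adjusted p = 0.692 with an estimated correlation). MT-TV had a value of -5.48 (adjusted p = 0.128), or -4.24 without control 2 and -6.13 without control 1. Transfer RNA genes made up 8.99% and 11.9% of the mtDNA counts in the controls and 2.67% and 3.17% at 100 µM.

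Of 18 integrated stress response genes, the targets of the ATF4 pathway, 0 passed, also adjusted over the list alone, while 17 were fitted above 0, with a median of 2.31. The list ranked higher in camera (adjusted p = 0.0414, then 0.0534 to 0.122 without any 1 of the 6 libraries, and adjusted p = 0.692 with an estimated correlation). STC2, a secreted glycoprotein, had 3214 ± 339 CPM at 100 µM and 326 ± 368 in the controls (2.47 ± 1.31, adjusted p = 0.340), a value of 5.28 without control 1 and 1.71 without control 2. All 27 genes of the list, tested or not, took 1.47% and 1.41% of the counts at 100 µM and 0.361% and 0.412% in the controls. MAP2K3, a kinase upstream of p38, had 787 and 420 counts at 100 µM and 0 in both controls, at least 34.2-fold higher (lower 95% limit 28.3). ODC1, the rate-limiting enzyme of polyamine synthesis, and RYBP, a Polycomb protein, had ratios of 245 (43.9 to 9676) and 250.4 (44.9 to 9895), each with 1 control count, and adjusted p = 0.204 for all 3 genes.

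The remaining 26 lists did not pass in camera, with a smallest adjusted p of 0.128. The medians were 0.13 for 17 complex I genes (adjusted p = 0.845), 1.06 for 30 genes of complexes II to V (0.502) and 2.26 for 9 genes of mtDNA expression (0.156), with 0 members passing in each. NDUFB9 had a value of -3.02 (adjusted p = 0.331), or 1.27 without control 2, and COX4I1 -0.98 (0.662). LRPPRC had a 100 µM to control ratio of 26.9 (9.18 to 131, 3 control counts; adjusted p = 0.309). For 10 PPARα targets the median of 0.58 differed in sign from the test's downward direction (adjusted p = 0.985), and ANGPTL4 had a value of -0.08 (0.975).

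The median of all genes was 0.35 with TMM, -0.05 with DESeq2 size factors and 1.02 with library sizes alone, and the first of these alternatives called 4 genes, all mtDNA and all lower, MT-ND2, MT-ND5 and MT-TV among them. Calls numbered 42 without control 1, of which 41 were lower and 27 mtDNA genes, and 43 without control 2, of which 42 were lower and 19 mtDNA genes.

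At 100 µM against 10 µM, all 13 mtDNA protein genes and 20 of the 22 mitochondrial transfer RNA genes were lower at 100 µM. MT-ND5 fell by 6.53 ± 0.63 log2 units (SE, n = 2 per group; edgeR, adjusted p = 0.00126) and MT-CO2, with the smallest difference of the 13, fell by 2.61 ± 0.46 (0.0178). Among nuclear genes, GDF15, a secreted stress cytokine, had 4407 and 3280 counts at 100 µM and 0 in both 10 µM libraries. It was at least 54.8-fold higher (lower 95% limit 43.6, adjusted p = 0.0304). NDRG1 rose by 5.99 ± 0.76 (adjusted p = 0.00323), or 5.59 without 10 µM replicate 1 and 6.68 without 10 µM replicate 2. In all 91 genes passed, 24 higher, all nuclear, and 67 lower, of which 33 were encoded by mtDNA and 34 by the nucleus.

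For the mtDNA protein genes the median was -5.11, or -6.09 with DESeq2 size factors (camera, adjusted p = 4.80e-22, and adjusted p = 0.285 with an estimated correlation), and all 13 were also lower adjusted over the list alone. The values included -5.90 for MT-ND2, -4.97 for MT-ND1, -6.31 for MT-ND6, -3.81 for MT-ND4, -7.67 for MT-ND3, -6.28 for MT-ND4L, -5.11 for MT-CYB, -2.78 for MT-CO1, -3.49 for MT-CO3, -4.69 for MT-ATP6 and -6.78 for MT-ATP8. For the transfer RNA genes the median was -9.03, with 22 lower adjusted over the list alone (adjusted p = 4.19e-41, and adjusted p = 0.285 with an estimated correlation). MT-TV had a value of -8.99 (adjusted p = 0.00323), or -8.35 without 10 µM replicate 2, MT-TF -9.88 (0.00342) and MT-TS1 -9.94 (0.00739).

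Of 18 integrated stress response genes, 1 was higher over all genes (GDF15) and 12 adjusted over the list alone. Their median was 8.66, or 3.84 with 9 members at their bound (camera, adjusted p = 0.0143, and adjusted p = 0.766 with an estimated correlation), and the call ended without control 1 (0.0789), control 2 (0.0758) or 10 µM replicate 2 (0.0773). Of 24 glycolysis and hypoxia genes, 3 were higher over all genes and 19 adjusted over the list alone, with a median of 5.29, or 4.13 at the bound of 6 members (adjusted p = 0.00306, then 0.0881 without control 1, 0.0835 without control 2, and adjusted p = 0.285 with an estimated correlation). Besides NDRG1 these were ENO1 (5.56) and LDHA (5.20), the glycolytic enzymes enolase and lactate dehydrogenase A. Of 44 large-subunit ribosomal proteins 1 was higher, RPL8, at least 38.6-fold (lower 95% limit 31.5, adjusted p = 0.0380), and 30 were higher adjusted over the list alone, with a median of 4.91, or 3.76 with 14 members at their bound (adjusted p = 0.000357, and adjusted p = 0.285 with an estimated correlation). Of 31 small-subunit proteins 0 passed over all genes and 22 were higher adjusted over the list alone, with a median of 5.04, or 4.03 with 10 members at their bound (adjusted p = 0.00177, and adjusted p = 0.348 with an estimated correlation). Both ribosomal calls ended without either control (0.0678). The shared floor for genes at 0 also limits the ranks of the stress response, glycolysis and ribosomal lists here. A gene without a count at 10 µM could differ only by its level at the higher dose. Whether abundance accounts for these ranks was not tested. RPS3 had a value of 3.89 (adjusted p = 0.125), between 3.19 and 5.28 without a library.

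Other nuclear genes higher at 100 than at 10 µM were PSAP, the precursor of the lysosomal saposins, at least 51.9-fold (adjusted p = 0.0380), the immediate early gene IER3, at least 32.1-fold (0.0408), and AHNAK, at least 21.96-fold (0.0408), with lower 95% limits of 40.9, 25.6 and 18.5. ERRFI1, an inhibitor of the epidermal growth factor receptor, had a 100 to 10 µM ratio of 188 (33.7 to 7429, 1 count at 10 µM), the actin-binding TMSB10 133 (36.8 to 1099, 2 counts) and ANGPTL4 68.1 (18.8 to 562, 2 counts), with adjusted p-values of 0.0408 or 0.0429 in edgeR. Of the nuclear genes lower at 100 µM, the potassium channels KCNT1 and KCNK3 had 0 counts in both 100 µM libraries and 4 and 68, and 31 and 24, at 10 µM (adjusted p = 0.0392 and 0.0380). Against 3 counts KCNK3 was at least 887-fold lower, and KCNT1 at least 1397-fold over both 10 µM libraries but 107-fold with replicate 1 alone. The peptidase ACE (at least 629-fold), the cadherins CDH15 (595) and CDH22 (549), FAM110D (416, or 240 with replicate 1 alone) and the glutamate receptor GRM4 (404) were also without a count at 100 µM, each with adjusted p = 0.0408. With the counting error of the 10 µM libraries included, the lower 95% limits were 688 for KCNK3, 494 for ACE, 429 and 416 for the cadherins, 287 for FAM110D and 300.2 for GRM4. Without a count at 100 µM, these genes passed the filter only through counts in the shallower libraries, where few counts give a high CPM. They belong to the nuclear genes without a count at 100 µM described further below. The kinase AATK had a 10 to 100 µM ratio of 3627 (632 to 145134, 1 count at 100 µM).

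The other 23 lists did not pass in camera, while fry, with the median of all genes at 3.52, called 26 lists higher. The medians were 3.63, or 2.22 at the bound, for complex I (camera, adjusted p = 0.709), 8.71, or 2.14 at the bound, for complexes II to V (0.137, then 0.0472 without 10 µM replicate 2), and 3.43, or 1.07 at the bound, for mtDNA expression (0.679), with 0 members passing over all genes. NDUFB9 had a ratio of 17.5 (4.83 to 144, 2 counts at 10 µM; adjusted p = 0.159), COX4I1 of 74.1 (13.3 to 2929, 1 count; 0.0766), and LRPPRC a log2 value of 0.61 (0.802). Among 10 PPARα targets 1 was higher (ANGPTL4), and the median of 5.23, or 1.28 at the bound, differed in sign from the downward test (adjusted p = 0.787).

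The median of all genes was 3.52 with TMM and 2.54 with DESeq2 size factors, the split of 24 higher and 67 lower became 6 and 73 with the latter, and the calls numbered 0 without either 10 µM library, 12 and 13 without 100 µM replicate 1 and 2, 705 without control 1 and 881 without control 2.

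The fold changes of both doses against the shared controls had a Pearson correlation of 0.351 across 3180 genes, which are not independent replicates. Unchanged groups simulated against the same controls gave 0.441 ± 0.0172 (SD of 30 simulations). The covariance was 6.27, against 2.07 ± 0.131 in the simulations, a difference of 4.20, and 56.1% of genes had the same sign at both doses, against 64.2% simulated. With the controls split, 1 library for each dose, the correlation was -0.0561 or 0.103. The observed correlation was thus no larger than shared controls alone gave in the simulations, although the covariance was larger. The simulations gave all groups the same spread per gene. In the data the biological coefficient of variation was 1.37 in the controls, 1.55 at 10 µM and 0.580 at 100 µM. The simulated values are therefore an inexact reference. These values do not show a response common to both doses. MT-ND5 had values of 3.22 at 10 µM and -3.31 at 100 µM. With 0 genes called at 100 µM, the called genes shared 0 in each direction, and independent lists would share 0.

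Some of these genes cannot be counted cleanly. KRT18, RPL37A, RPL8, RPS3, H3-3B, TMSB10, HNRNPH1, LDHA and ENO1 have near-identical copies or pseudogenes, and MT-ATP6 has a nuclear copy, MTATP6P1, on chromosome 1 (633696 to 634376). Nuclear copies of other mtDNA genes are not listed here, so those genes are not shown to be counted cleanly. MT-ATP8 (8366 to 8572) overlaps MT-ATP6 (8527 to 9207), and MT-ND4L (10470 to 10766) overlaps MT-ND4 (10760 to 12137). Their values are uncertain, as are those of the short transfer RNA genes, since the strand and overlap settings of the counting were not given in the sources used here.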

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

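The tests of the mitochondrial profile in this part were chosen after the result was seen, and the test on silent nuclear genes was written before it.

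At 10 µM many nuclear counts lay on genes that had no count at 100 µM or were too low to be tested. Protein-coding nuclear genes without a count in either 100 µM library, 7739 in all, took 18.7% and 15.0% of the nuclear counts at 10 µM, a mean of 16.8%, against 1.04% and 3.13% in the controls, a mean of 2.08%. Of these genes 29 were tested, among them KCNK3 and ACE, and the untested ones took 17.1% and 12.3% at 10 µM and 0.978% and 3.002% in the controls. All genes too low to be tested together took 64.6% and 56.2% of the nuclear counts at 10 µM, a mean of 60.4%, against 16.5% and 22.8% in the controls, a mean of 19.6%, and 19.9% and 17.97% at 100 µM. Both signals were singled out because they come wholly or mostly from genes that were not tested and lay above the level in the controls.

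The higher mtDNA share at 10 µM went with nearly even counts over the mtDNA genes and with counts on nuclear genes that the 100 µM libraries did not show. An equal rise of all mtDNA transcripts would have kept the unevenness of the other groups, and it is argued against by an SD of log2 counts per kilobase over MT-ND1 to MT-CYB that was at most 0.375 times that of the controls. Reads from DNA carried into the libraries could give both, since the higher SD of the 10 µM libraries was 0.229. Transfer RNA genes took 12.4% and 12.9% of the mtDNA counts, beside 11.7% of the length of the 35 genes. MT-ND6 on the minus strand was as high per kilobase as the other 12 genes. That value bears on both strands only if reads were counted by strand, and this setting was not given. For the nuclear part no value decided, because the silent genes reached 0.405 and 0.226 times the counts per kilobase of the 1000 most abundant genes, between the bounds set for and against. Unprocessed precursor RNA, and an effect of 10 µM GenX on these cells, stay open and untested, because dose, depth and this profile moved together in the 10 µM libraries. Nor can nuclear changes that involve these libraries be told apart from a different amount of nuclear and cytosolic RNA in the mitochondrial preparations, which was not tested.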

How the results depend on the processing

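Thinning to the shallowest total and leaving out the 10 most abundant genes of each library were chosen after the results were seen; the other alternatives were planned. The medians of the 13 mtDNA protein genes kept their direction in the 6 fits without a library and in 6 other alternatives, between 2.53 and 3.75 at 10 µM, -1.60 and -2.76 at 100 µM and -4.78 and -6.09 at 100 against 10 µM, and were 0.32, -0.87 and -0.99 scaled to the summed counts of these genes, a scale that removes a change common to all of them. Of the values of named genes under an alternative, 793 were the same, 73 passed newly, 226 no longer passed and 12 turned, and 86 of 92 genes in a comparison never turned. Of 51 calls of named genes, 0 held in all alternatives.

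Calls at 10 µM against control, 19 in the report, were 7 with library sizes alone, 7 with no filter and 95 at a mean of at least 5 CPM, all lower, so the 7 higher mtDNA genes were lost there and in the Wald test. They were 12 with only 4 libraries, 0 without the most abundant genes and 82 with thinned libraries (54 higher, 31 of them mtDNA, and 28 lower). At 100 µM against control, 0 became 4 with DESeq2 size factors and 11 in DESeq2's Wald test. At 100 against 10 µM, 91 (24 higher and 67 lower) became 925 in the Wald test (12 and 913), 3 with no filter (3 and 0), 291 at 5 CPM (201 and 90) and 797 with only 4 libraries (631 and 166), so in the last 3 more genes were higher than lower. An estimated correlation left 0 lists in each of the 3 comparisons. For the large-subunit ribosomal and glycolysis lists that correlation, 0.00537 and -0.0125, was below the preset 0.01. Their calls were thus not lost to a higher correlation. By contrast, fry called 22 lists at 10 µM against control, 3 at 100 µM and 28 at 100 against 10 µM. At 100 µM against control fry dropped the mtDNA protein and stress response lists (0.0680 for both). The correlation of fold changes was 0.329 with library sizes alone, 0.275 at 5 CPM, and -0.0561 and 0.103 with the controls split. For filters the number of genes tested differed by construction; otherwise the cause was not tested.

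LRPPRC at 100 against 10 µM turned to -0.49 with DESeq2 size factors and -0.086 in the Wald test. Against control at 100 µM, ANGPTL4 turned to 0.41 with library sizes alone and 0.033 with only 4 libraries, and MT-CO1 to 0.33 with library sizes alone; none of these had passed, and the cause was not tested.

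Leaving out 1 library at a time gave 0 to 624 genes at 10 µM against control, 0 to 43 at 100 µM and 0 to 881 at 100 against 10 µM, where 2 to 6 lists were called, and correlations of 0.314 to 0.561. In these fits LRPPRC ranged from -6.32 to 10.02 at 10 µM against control and from -0.20 to 10.65 at 100 against 10 µM. Against control at 100 µM, NDUFB9 ranged from -3.98 to 1.27, ANGPTL4 from -0.41 to 0.47 and MT-CO3 from -0.93 to 0.050. The library left alone in its group was assumed to vary like the other groups.

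With a replicate block the counts were 75 at 10 µM and 22, all lower, at 100 µM against control and 136 at 100 against 10 µM. Libraries of the same number did not deviate together (correlations 0.000331, 0.00315 and -0.0222). These values cannot exclude pairing, since noise between shallow libraries could hide it, and the labels did not say how the replicates relate.

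The share of mtDNA without its ribosomal genes was not run, since these genes were not analysed here. Depth limits the 10 µM group most: a gene below 68.9 or 102 CPM may go uncounted there, beside 1.40 and 2.24 CPM at 100 µM, and thinned to 1 depth the libraries left 652 genes to test and 82, 0 and 71 calls.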

Other observations

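Tests of the controls' mtDNA profile, their spread and the share of their most abundant genes were chosen after the results were seen. The test without the most abundant genes was also added after the data were seen, with its bounds written before its own result.

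Of 8 tested long noncoding RNAs kept in the nucleus, 2 were lower at 10 µM than in the controls, and in camera the list did not rank apart (adjusted p = 0.819). MALAT1 and NEAT1, which forms paraspeckles, lie outside the rule for named genes and were chosen after their values were seen. MALAT1 had a log2 fold change of -8.15 ± 0.74 at 10 µM against control (SE, n = 2 per group; edgeR, adjusted p = 0.00130) and NEAT1 -6.15 ± 0.85 (0.0153), and both were higher at 100 than at 10 µM, by 5.68 ± 0.67 and 5.24 ± 0.82. All 14 RNAs of this list together took 14.004% and 5.60% of the counts in the controls, of which MALAT1 took 13.5% and 4.61%, against 0.156% and 0.109% at 10 µM and 3.604% and 3.26% at 100 µM. Also outside the rule, FN1 (fibronectin) and GPC3 (glypican 3, abundant in liver carcinoma) were lower at 10 µM than in the controls, at -5.82 ± 1.04 and -5.37 ± 1.00 (adjusted p = 0.0414 for both).

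At 100 µM against control, 0 genes passed in several further lists, and none ranked apart in camera. The median was 2.31 over 20 antioxidant genes of the NRF2 response (adjusted p = 0.128), 2.14 over 13 mitochondrial ribosomal proteins (0.249; fry called these 2 lists, at 0.0283 and 0.0276), 2.57 over 16 genes of the unfolded protein response (0.227) and 1.74 over 15 immediate early genes (0.156). Cytosolic ribosomal proteins had medians of -0.06 and -0.40 (0.204 and 0.227), and glycolysis genes a median of 0.47 with a downward test (0.864). Few markers of other cell types had enough counts, with 1 fibroblast, 1 blood and 2 endothelial genes tested, and 6 cholangiocyte genes gave adjusted p-values of 0.146, 0.742 and 0.234 in the 3 comparisons. MT-TL1, the transfer RNA gene next to the 3′ end of MT-RNR2, had 757 and 774 CPM at 100 µM, 4569 and 5383 at 10 µM, and 744 and 756 in the controls. MT-TL1 and MT-TY were the 2 transfer RNA genes that did not pass at 100 against 10 µM.

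The lower mtDNA values at 100 µM against control may come in part from a more even mtDNA background in the controls. With each library described as a mixture of the 100 µM profile and counts spread by gene length, the even part was 46.4% and 76.2% of the mtDNA counts in the controls and 98.6% and 97.9% at 10 µM, while the 1.37% and 0% at 100 µM follow from the profile used. For each gene's share of the mtDNA counts, the predicted changes explained an R2 of 0.787 of those observed over 35 genes, MT-ND3 and MT-ND5 included. Shares remove a change common to all mtDNA genes, so the R2 does not bear on their overall level. The 100 µM profile entered both the predicted and the observed changes. The mixture was also fitted to the same counts, so the more even background is a hypothesis. The source of an even background, and an effect of 100 µM GenX on transcripts such as MT-ND2, stay open and untested.

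That 0 genes passed at 100 µM against control (573 at an unadjusted p under 0.05 in edgeR, 11 in DESeq2) may come in part from the spread between the 2 controls. Their biological coefficient of variation was 1.37, 2.36 times the 0.580 of the 100 µM libraries. The 10 µM libraries had 1.55, and 91 genes passed at 100 against 10 µM. That comparison cannot tell whether spread prevented calls against control. Its median log2 fold change was 3.52, beside 0.35 against control, and both tests used 1 shared estimate of the spread. A few genes taking most of the counts in control 1 is argued against, since its 10 most abundant genes took 23.7% of them, while the 0 genes that passed without the most abundant genes of every library decide nothing, being 0 with them too. The controls also differed in depth, 240683 and 60854 counts, and at 1 common depth the coefficients over 1659 abundant genes were 1.37 and 0.281. A small or absent effect of 100 µM GenX on most genes stays open, since of genes changed 4-fold in simulated data 1.49% were recovered.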
